A study of Arabidopsis thaliana with 8 samples.

How the data were processed

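Total RNA of whole 2-week-old seedlings was labelled with Cy3 from 1 µg, per the labels' protocols, and each of 8 samples was hybridised to one array of a 1-colour Agilent design with 39102 spots. Agilent Feature Extraction 9.1.3.1, per the submitters' processing notes, produced the scanner files. Per the file headers, the processed signal is an intensity on a linear scale after spatial detrending and background subtraction, without scaling between arrays, and the median spot and background signals are raw intensities. The deposited table of the whole series holds an intensity too. Set against the scanner values, its columns equal the processed signal divided by one constant per slide, 1340.6 for 35S:WIN1 and 1311.9 for the control, within 0.0219%. How these constants were chosen is not given in the sources used here. The column medians of that table were 0.0464, 0.0588, 0.114 and 0.125 for 35S:WIN1 replicates 1 to 4 and 0.0853, 0.111, 0.112 and 0.126 for the control, so its scale is linear and uncentred, and its between-array scaling stays as scanned.

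Groups and replicate numbers came from the sample titles. The titles call the reference samples vector control and the genotype field calls them wild type. Values were log2 of the processed signal minus each array's 75th percentile of it over non-control spots. Spots with outlier marks were left out, spots of one probe were averaged, and no probe was saturated. The files name 26236 of the 37478 probes by a locus, covering 25665 loci. The other 11242 probes did not enter the gene tests. A gene was its probe with the highest mean signal, kept where that probe was well above background on at least 4 of 8 arrays, which left 20445 genes. For 2 of these a group had no value, so 20443 were tested, 20326 of them found in the reference table of assembly TAIR10.1, which was used for names and for the order of neighbours. Its coordinates are not printed because the files name no build. Of 522 tested loci with several probes, 7 had probes that passed an unadjusted p of 0.05 in opposite directions.

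Differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 (tables were read with version 1.17.8 of the data.table package), two-sided and adjusted by the Benjamini-Hochberg method, at an adjusted p of 0.05. A probe not well above background on every array of a group has only a bound there. Its fold was computed from the brighter group's mean against the dimmer group's mean with each array's value raised to at least the lowest signal among probes well above background, and is written as at least N-fold. This held for 159 of the genes called. For a named gene above background on only some arrays of a group, the fold with values raised to that floor stands beside the log2 difference, which rests in part on values below background. The 18 gene lists, with 358 members of which 336 were tested, were fixed before the data were examined and were tested with camera at a preset correlation of 0.01, on the 20270 genes with complete values. With an estimated correlation 0 of the 10 lists called by camera passed (3 of the 18 lists at an unadjusted p of 0.05), and with fry, which asks whether a list's genes move one way on balance, 14 lists passed. The 33 families were matched on names in the reference table, since the files carry no descriptive text, and 3 with under 5 tested genes were left out. They were compared with all genes tested, although only the 9181 with name text (9195 with every gene matching a family kept) could readily match. Against either of these 2 sets, chosen after seeing the data, the same 19 tests passed.

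Genes named in the text followed a rule fixed before the data were examined. It takes WIN1, the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05 whose 4 arrays of one group all lay above the 4 of the other and were all well above background in the higher group, and up to 4 members of each list with the smallest p. Other genes named are said to be chosen afterwards.

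On simulated arrays with the means and spreads of these 20443 genes and 50 changed genes at each of 4 fold sizes, the fit of 35S:WIN1 against vector control recovered 26% of 1.5-fold, 52% of 2-fold, 66% of 4-fold and 94% of 8-fold changes, and 4.8% of its calls were false. In a simulated set of lists, the shifted list of 20 genes passed and 0 of 20 unshifted lists did. The noise was drawn for each gene independently and without array effects, while the estimated correlation of the real lists reached 0.528. Far fewer genes were changed than the 35.3% called in the real data. These runs therefore do not measure the share of false calls in the real data. The number of arrays limits the precision.

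Alternatives fixed before the data were examined were quantile normalization, median centring, normexp background correction with an offset of 50, the deposited values, other detection filters, the mean over probes, other variance models, array weights, a replicate block, other thresholds, other set tests, and leaving out each array. A spike-in scale, added later, subtracts the median of the 8 spike-in probes above background on all arrays in place of the 75th percentile. Ranges of adjusted p over all settings leave it out, since its test differs. The mean spot signal is not in the files used, so normexp ran on the median spot signal. A slide block could not be fitted because each slide held 1 group.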

Results

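Transcript levels were measured in whole Arabidopsis thaliana seedlings of the Columbia-0 ecotype that carried WIN1, a transcription factor gene of the AP2/ERF class known for its part in cuticle formation, behind the strong viral 35S promoter. They were set against seedlings labelled as vector control, whose genotype field reads wild type. Seedlings were 2 weeks old and had grown on agar with 1% sucrose in 16 h light and 8 h dark at 23 degrees Celsius. Each group had 4 samples, each hybridised to its own 1-colour array of 37478 probes. Per the labels, many seedlings shared a plate and several were taken per sample, and nothing says that the samples came from separate plates, so p-values measure the spread between these samples, which may be technical. The 75th percentile of the processed signal ran from 996.7 to 2490 on the 35S:WIN1 arrays and from 1790 to 2354 on the control arrays, and 58.9% to 65.4% of probes were well above background. Arrays of one group correlated at r = 0.948 to 0.987 across genes and arrays of different groups at 0.885 to 0.927. The 8 spike-in RNAs above background on all arrays were higher on average relative to the 75th percentile in 35S:WIN1, by a median of 1.58 on the log2 scale. The array medians of the groups overlapped, at 2.77 on 35S:WIN1 replicate 4 and 2.78 on vector control replicate 1. All 35S:WIN1 arrays lay on one slide and all control arrays on another, so slide and genotype cannot be told apart in any comparison given here.

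The first question was whether the transgene was expressed. WIN1 (AT1G15360, also SHN1) was strongly higher in 35S:WIN1, at 4.85 ± 0.83 (SD, n = 4) on the log2 scale relative to the array's 75th percentile, against -8.21 ± 1.49 (SD, n = 4) in the control. The log2 difference was 13.06 with an SE of 0.73 (limma, adjusted p = 2.88e-05). The probe was well above background on 4 of 4 arrays of 35S:WIN1 and on 1 of 4 control arrays, and with values raised to each array's detection floor the fold was 3836. The locus is not given in the labels. A second gene that has carried the name WIN1, AT1G80600, was lower by a small margin, with a log2 difference of -0.78 and an SE of 0.19 (adjusted p = 0.0161).

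**Figure D1:**
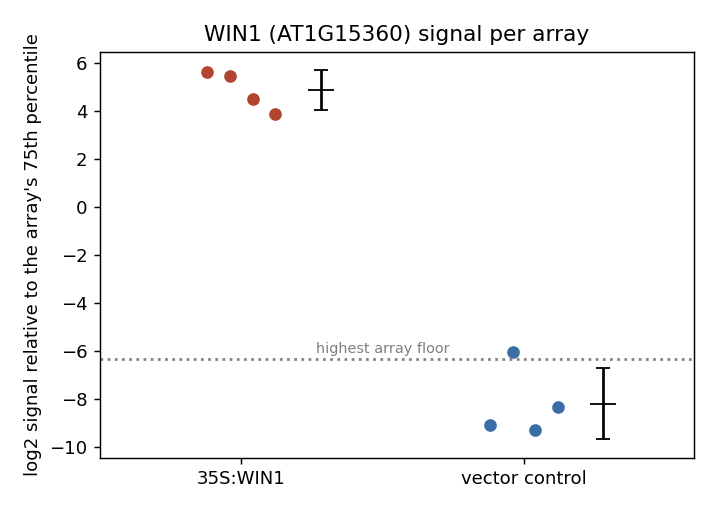
Signal of WIN1 (AT1G15360) on each array, as log2 relative to the array's 75th percentile, with 1 point per array and the mean with its SD beside each group. The 35S:WIN1 arrays averaged 4.85 and the control arrays -8.21, and the dotted line marks the highest detection floor of the 8 arrays.

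The second question, the one the design text names, was which other transcripts differed between the lines. AT1G49570, a peroxidase gene, JRG21, a jasmonate-regulated gene, and CYP71A13, of camalexin synthesis, were among the genes with the largest fitted rises. CYP735A2, of cytokinin synthesis, and ESP, whose product diverts glucosinolate breakdown, were among those with the largest fitted falls. Of 20443 genes tested, 3078 were higher and 4138 lower in 35S:WIN1 (limma, Benjamini-Hochberg adjusted), which is 35.3% of the genes. At least 2-fold changes were found for 1581 higher and 1527 lower genes. The groups did not overlap for 7306 genes, 35.7% of those tested, where chance gives 2.86%. The deposited values, which are not scaled between arrays, gave 2993 genes, 905 higher and 2088 lower, a share of 30.2% higher against 42.7%. Without the 2 dimmest arrays, 35S:WIN1 replicates 1 and 2, 4318 genes passed, and with vector control replicate 4 as the only control 427 passed.

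Directions in this text are relative to each array's 75th percentile and depend on that choice. With each array's spike-in median in its place, a scale tried after seeing the data, all differences shift by -1.64, which puts the median of all genes at -1.68. Of the 3078 genes called higher 2193 then lie below 0 and 885 above. Of 39 named genes called higher 10 then lie below 0, namely LACS2, GPAT4, KCS3, CER6, AOS, EDS5, EDS1, CYP79B2, CYP79F2 and THAH. All 50 named genes called lower stay below 0, which a downward shift fixes in advance and which says nothing about their robustness. The medians of the cutin, jasmonate and abscisic acid lists became -1.28, -0.33 and -0.38, below 0 but above the median of all genes. A shift shared by all genes also fixes that order in advance. The data do not decide between the 2 scales. Each sample was labelled from 1 µg of total RNA, so neither scale gives the amount of transcript per seedling.

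The 12 largest rises were ranked by fitted differences, which for a probe below background have no order of their own. Besides WIN1 they took in AT3G05950, at least 1083-fold higher (adjusted p = 2.77e-05) and well above background on 0 of 4 control arrays. The peroxidase genes AT1G49570 and AT5G19890 rose by log2 differences of 8.76 (SE 0.28) and 8.71 (SE 0.42). JRG21, a jasmonate-regulated gene, rose by 8.56 (SE 0.62). GSTU3, a glutathione transferase gene, was at least 97.01-fold higher, and CYP71A13, of camalexin synthesis, at least 81.9-fold higher. The beta-glucosidase gene BGLU24 rose by 10.67 (SE 0.59), scpl30, a carboxypeptidase-like gene, by 9.76 (SE 0.61), and AT5G22430 by 8.21 (SE 0.73), with 1, 2 and 1 of 4 control arrays above background. With values raised to each array's detection floor the folds of these 3 were 526.5, 511 and 164. HR4 and CEJ1 completed the set, with log2 differences of 9.27 (SE 2.21) and 8.64 (SE 1.88) and 2 and 1 of 4 control arrays above background, or 279-fold and 151-fold with the floor. Both lie in a run of neighbouring genes on chromosome 3 that was near background on vector control replicates 1 to 3 but not on replicate 4. The size of their differences therefore rests mainly on 3 control arrays. HR4 stood at 1.38 on vector control replicate 4 against a 35S:WIN1 mean of 3.17, and CEJ1 at -0.45 against 1.59. Without the 2 dimmest arrays neither passed (adjusted p = 0.0782 for HR4 and 0.0641 for CEJ1), and against vector control replicate 4 alone HR4 had a log2 difference of 1.80 (adjusted p = 0.117). Over all settings the adjusted p of HR4 ran from 1.36e-04 to 0.117 and that of CEJ1 from 4.26e-07 to 0.0641.

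The 12 largest falls were ranked in the same way, so that a gene measured on all 8 arrays, such as CYP86A1 at 18.1-fold lower, can exceed the bound of a gene among them. AT1G31690 had a log2 difference of -6.94 (SE 1.08, adjusted p = 0.00234). ESP, which encodes the epithiospecifier protein, fell by 6.10 (SE 1.34), and CYP735A2, an enzyme gene of trans-zeatin synthesis, fell by 5.52 (SE 0.53). These 3 genes were above background on 2, 2 and 1 of 4 arrays of 35S:WIN1, and with the floor they were 83.6-fold, 65.7-fold and 19.96-fold lower. The fall of ESP was uneven, with -6.13 and -6.99 on 35S:WIN1 replicates 1 and 2 and -2.30 and -0.49 on replicates 3 and 4. Its control mean was 2.13. The peroxidase gene AT2G39040 was at least 19.7-fold lower and AGP30, an arabinogalactan protein gene, at least 23.0-fold lower. AT1G52820, SP1L5, AT2G28270 and AT2G22590 were lower by at least 19.8, 20.2, 11.3 and 19.4-fold. AT3G21950 and CYP712A1, each above background on 1 of 4 arrays of 35S:WIN1, had log2 differences of -5.88 and -5.65, or 26.5-fold and 28.3-fold lower with the floor. PCC1, above background on 2 of 4, fell by 5.91 (SE 1.69, adjusted p = 0.0278), or 43.1-fold with the floor. The call for PCC1 was lost without 35S:WIN1 replicate 1 or 2 or vector control replicate 3 or 4, with adjusted p from 0.0632 to 0.0691, and over all settings tried its adjusted p ran from 0.00260 to 0.180. Near-identical gene copies were not separated by sequence, so a probe's signal may include a paralog's.

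Genes of cutin, the polyester of the shoot cuticle, moved both ways with more members higher. Of 21 members tested, 8 were higher and 3 lower, or 10 and 5 when adjusted over the list alone, and the list as a set was higher (camera adjusted p = 0.0261, but adjusted p = 0.361 with an estimated correlation). The cytochrome P450 genes CYP77A6 and CYP86A4 rose 9.44-fold and 7.75-fold (log2 SE 0.26 and 0.23), and LACS2, an acyl-CoA synthetase gene, 2.79-fold. GPAT4, an acyltransferase gene, rose by a log2 difference of 1.58. CYP77A4 was among the 3 that fell, with a log2 difference of -2.77. The list's median was 0.36, and on the deposited values it was -0.04, which is 0.40 above the median of all genes in both. Scaling whole arrays moves all genes alike, so this distance could hardly change. The set did not pass without 35S:WIN1 replicate 4 (adjusted p = 0.0700) or under normexp background correction (adjusted p = 0.0535), and over all camera settings its adjusted p ran from 0.0106 to 0.361, the latter with the estimated correlation. Of 31 wax genes, 11 were higher and 8 lower, or 12 and 8 adjusted over the list alone, and the set did not pass by camera (adjusted p = 0.0629), though it did without vector control replicate 4 (adjusted p = 0.0483, and up to 0.361 over all camera settings). The elongase genes KCS3 and CER6 rose 2.16-fold and 1.76-fold, and KCS16 and KCS8 had log2 differences of -2.94 and -1.97.

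Genes of suberin, the polyester of root barriers and seals, fell together. Of 19 members 15 were lower and 1 higher, counts that were the same when adjusted over the list alone (camera adjusted p = 5.68e-06, adjusted p = 0.335 with an estimated correlation), and their median was -2.25, or -1.98 with the 1 member below background in a group set to its bound. CYP86A1 and CYP86B1, fatty acid hydroxylase genes, had log2 differences of -4.18 (SE 0.29) and -3.99 (SE 0.38), GPAT5 -3.33 (SE 0.34) and ASFT, a feruloyl transferase gene, -1.95 (SE 0.18). Root tissue markers did not pass as a set beside this (camera adjusted p = 0.148). Of 21 of them 6 were higher and 2 lower, or 6 and 3 adjusted over the list alone, and their median was 0.27. MRN1, THAS1 and THAH, genes of triterpene synthesis in the root, rose by 6.01, 1.68 and 1.39, MRN1 with 1 of 4 control arrays above background and 38.6-fold with the floor. NRT2.1, a nitrate transporter gene above background on 2 of 4 arrays of 35S:WIN1, had a log2 difference of -4.69, or 12.4-fold lower with the floor.

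**Figure D2:**
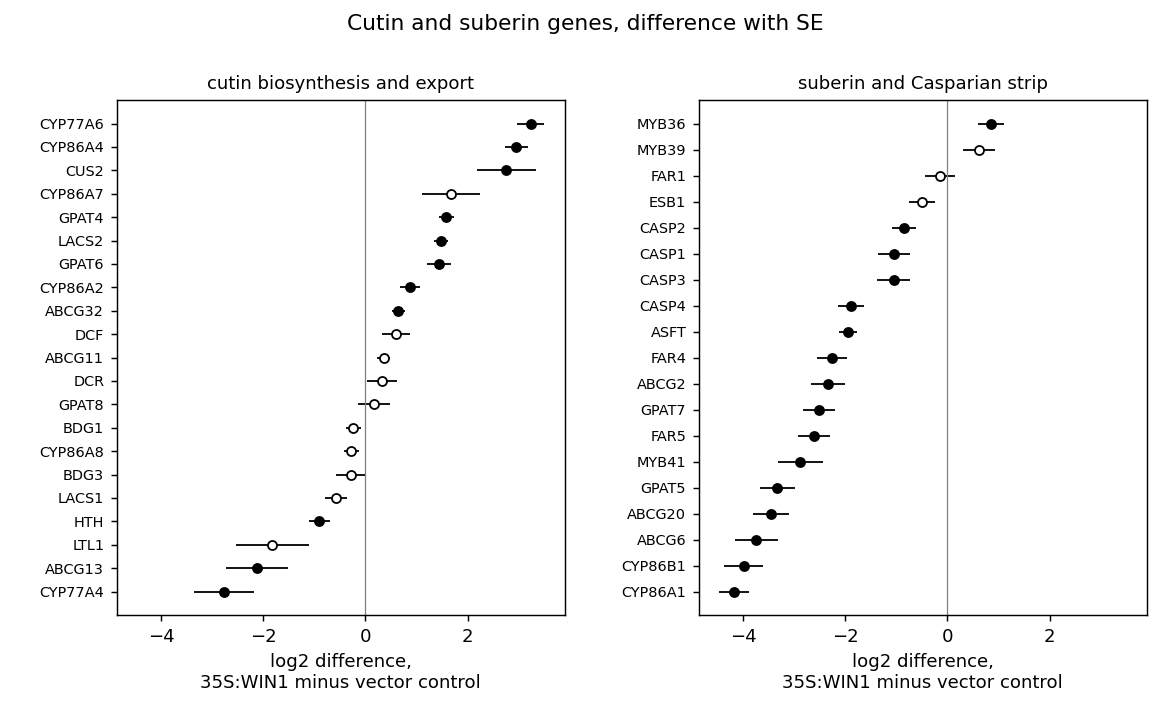
Log2 difference, 35S:WIN1 minus vector control, of each tested gene of the cutin list and of the suberin list, as points with the SE of the fit as bars, filled where the adjusted p was under 0.05. In the suberin list 15 of 19 members lay below 0 and passed, and in the cutin list 8 passed above 0 and 3 below.

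Regulators of cuticle and epidermis showed 2 higher and 8 lower of 16, the same when adjusted over the list alone, and did not pass as a set (camera adjusted p = 0.0629). Without 35S:WIN1 replicate 2 or vector control replicate 2 the set passed (adjusted p = 0.0493 and 0.0345), and over all camera settings its adjusted p ran from 0.0281 to 0.361. MYB96, an activator of wax genes, rose 9.25-fold (log2 SE 0.26). SHN2 and SHN3, the closest relatives of WIN1, had log2 differences of -5.20 and -3.17 and were above background on 1 of 4 arrays of 35S:WIN1 each, and with the floor they were 16.1-fold and 2.68-fold lower. MYB16 fell by 1.55. For SHN3 the call was lost under normexp background correction (log2 difference -0.10, adjusted p = 0.766, and from 6.12e-05 to 0.766 over all settings). Stomatal lineage genes fell, 13 of 17 lower and none higher, or 14 adjusted over the list alone (camera adjusted p = 2.34e-04, adjusted p = 0.335 with an estimated correlation). TMM, a receptor-like protein gene of stomatal patterning, fell by 2.21. EPF2, POLAR and BASL had log2 differences of -3.44, -3.19 and -3.52, EPF2 and BASL with 3 of 4 arrays of 35S:WIN1 above background and 10.8-fold and 9.30-fold lower with the floor. The fall was uneven, with list medians of -1.76 and -1.43 against the control mean on the 2 dimmest arrays, 35S:WIN1 replicates 1 and 2, and of -1.17 and -0.81 on replicates 3 and 4. Without those 2 arrays the list's median was -0.91 (camera adjusted p = 4.20e-05), and TMM, EPF2, POLAR and BASL stood at -1.72, -2.57, -2.20 and -2.51 and passed. Trichome patterning genes fell likewise, 8 of 12 lower and none higher, also when adjusted over the list alone (camera adjusted p = 3.64e-04, adjusted p = 0.296 with an estimated correlation), with a median of -0.93 without the 2 dimmest arrays (camera adjusted p = 2.78e-04). MYB23, GL2, GIS and TTG2 had log2 differences of -2.47, -2.26, -2.00 and -0.95, and TTG2 lost its call under normexp background correction (adjusted p = 0.0683, and from 0.00148 to 0.142 over all settings).

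Nuclear genes of photosynthesis were lower, 20 of 32 with none higher, also over the list alone (camera adjusted p = 2.06e-04, adjusted p = 0.361 with an estimated correlation). The photosystem genes PSBY, PSAL and PSAH2 had log2 differences of -1.05, -1.08 and -1.45 and LHCB6, a light-harvesting gene, fell by 0.66. Of 15 flavonoid genes, 6 were lower and none higher, also over the list alone (camera adjusted p = 0.0261, adjusted p = 0.486 with an estimated correlation). CHS, the gene of the entry enzyme, fell by 3.25 (SE 0.43), and CHI, F3H and FLS1 had log2 differences of -1.89, -2.96 and -3.33. The flavonoid set lost its camera call without vector control replicate 4 (adjusted p = 0.0630), with array weights (0.0532) and without the 2 dimmest arrays (0.0860), over a range of 0.00116 to 0.486 for all camera settings. Its medians against the control mean were -1.33 and -1.09 on 35S:WIN1 replicates 1 and 2, the 2 dimmest arrays, and -0.36 and -0.21 on replicates 3 and 4. On the control arrays they ran from -0.53 to 0.43. Cell division genes were slightly lower, 7 of 18 with none higher, also over the list alone (camera adjusted p = 0.0217, adjusted p = 0.486 with an estimated correlation), with AUR1 at -0.54, CYCD3-1 at -0.63, CDKB1-1 at -0.72 and PCNA1 at -0.63. That set lost its call without 35S:WIN1 replicate 4 (adjusted p = 0.0700) and on the deposited values (0.0653), over a range of 0.00287 to 0.535 for all camera settings. PCNA1 itself did not pass without 35S:WIN1 replicate 1 or 3 or vector control replicate 1 or 2, with adjusted p from 0.0567 to 0.0722, over a range of 0.0121 to 0.520.

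Jasmonate synthesis and response genes rose, 14 of 19 with none lower, also over the list alone (camera adjusted p = 5.68e-06, adjusted p = 0.296 with an estimated correlation). JAZ1, a repressor gene of the pathway that its own hormone induces, rose 19.6-fold (log2 SE 0.16), JAZ8 23.9-fold with 3 of 4 control arrays above background (23.2-fold with the floor), JAZ5 21.2-fold and AOS, an enzyme gene of jasmonate synthesis, 2.06-fold. Genes of abscisic acid, drought and cold moved both ways. Of 25 members 14 were higher and 7 lower, or 15 and 7 over the list alone (camera adjusted p = 0.00572, adjusted p = 0.302 with an estimated correlation). The cold regulator gene CBF1 rose by 7.58 (SE 0.62), with 1 of 4 control arrays above background and 108-fold with the floor, NCED3, the key gene of abscisic acid synthesis, by 3.16, RD22 by 2.87 and ABI1 by 1.65. COR15A, a target of CBF1, fell by 3.30, and was chosen for mention after its value was seen.

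The other lists did not pass by camera or were small. Salicylate and defence genes were 6 higher and 2 lower of 19, the same over the list alone (adjusted p = 0.0600), with CYP71A13 higher as above and EDS5, EDS1 and CBP60G higher by 1.35, 0.61 and 1.68. That set passed without 35S:WIN1 replicate 2 or vector control replicate 2 or 4 (adjusted p from 0.0267 to 0.0355, and from 0.0160 to 0.535 over all camera settings). Glucosinolate genes were 10 higher and 3 lower of 23, or 10 and 4 over the list alone (adjusted p = 0.0600). MYB51 and CYP79B2, of the indole branch, rose by 1.94 and 1.28, and of the aliphatic branch CYP79F2 rose by 1.03 and MYB29 fell by 1.57. That set passed without 35S:WIN1 replicate 2 or vector control replicate 1 or 3 (adjusted p from 0.0372 to 0.0493, and from 0.0369 to 0.335 over all camera settings). Wall loosening genes split 7 and 7 of 25, also over the list alone (adjusted p = 0.521), with XTH18 higher by 2.39 and EXPA15, XTH6 and EXPA5 lower, at -1.21, -1.42 and -1.59. Of 9 flower and flowering markers 3 were lower, also over the list alone (adjusted p = 0.0597), and the set passed without 35S:WIN1 replicate 4 or vector control replicate 4 (adjusted p = 0.00805 and 0.0355, and from 0.00805 to 0.486 over all camera settings). FUL fell by 3.62, with 3 of 4 arrays of 35S:WIN1 above background and 11.6-fold with the floor. SOC1 and SEP1 had log2 differences of -1.21 and -1.90, SEP1 with 3 of 4 such arrays and 3.45-fold with the floor, and each lost its call without any 1 array except 35S:WIN1 replicate 4 and vector control replicate 4. SEP1 also did not pass under normexp background correction (log2 difference -0.50, adjusted p = 0.267) or with no detection filter (0.0519). Without single arrays their adjusted p ran from 0.0565 to 0.0659 and from 0.0575 to 0.0981, over ranges of 0.00613 to 0.677 and 0.00504 to 0.562 for all settings. FT stood at -1.40 with an adjusted p of 0.122, and passed without 35S:WIN1 replicate 4 (0.0121, over a range to 0.688). Of 13 seed markers only LEC1 and FUS3 met the detection filter, which their 4 arrays of 35S:WIN1 alone fulfilled, so being high in that group helped to select them. They rose by 2.57 and 1.68, with 1 and 2 of 4 control arrays above background and 4.85-fold and 2.82-fold with the floor, also over the list alone (camera adjusted p = 0.0261, adjusted p = 0.296 with an estimated correlation), and the set lost its call under normexp background correction (adjusted p = 0.156) and without 35S:WIN1 replicate 4 (0.0665), over a range of 0.00128 to 0.296 for all camera settings. With no detection filter all 13 markers were tested and their median was 0.35 (camera adjusted p = 0.0330), with 3 called higher and none lower. The markers this added were well above background on fewer than 4 of 8 arrays, so that median rests mostly on signal near background. There the detection floor ran from -7.54 to -6.36 on the 35S:WIN1 arrays and from -7.65 to -7.12 on the control arrays. The median is thus no evidence of a rise of seed genes. None of the 12 reference genes passed (limma), 1 at an unadjusted p of 0.05, and their median was 0.05. UBQ10, at 0.40, passed under quantile normalization (adjusted p = 0.0150) over a range of 0.0150 to 1.00 for all settings. On the spike-in scale the median of the reference genes was -1.58. Of the genes named, LACS2, KCS3, CER6, LHCB6, AOS, EDS5, EDS1, CBP60G, CYP79B2, CYP79F2, AUR1, CYCD3-1, CDKB1-1, PCNA1, THAH, FUS3 and AT1G80600 did not pass on the deposited values. AT1G80600, HR4, CEJ1, PCC1, CYCD3-1, PCNA1, THAH, SOC1 and SEP1 did not pass without the 2 dimmest arrays, FUS3 did not under normexp background correction and PCNA1 did not under median centring.

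**Figure D3:**
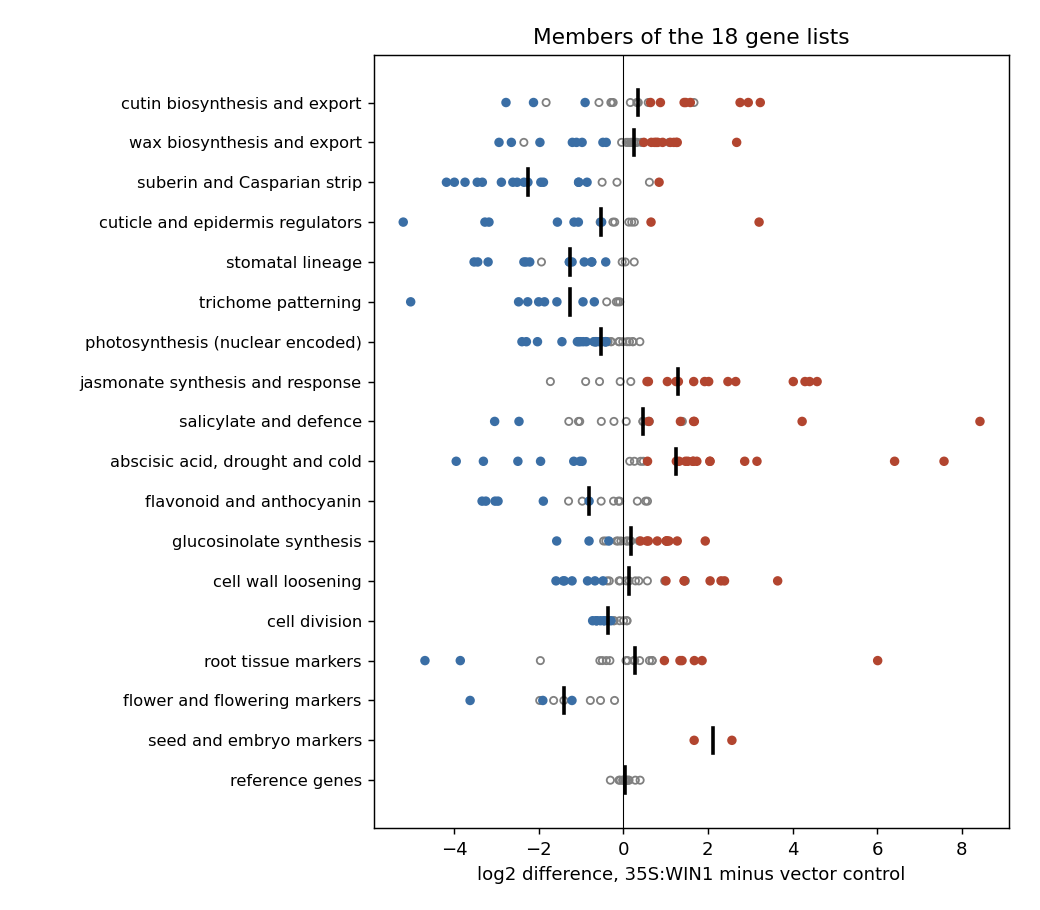
Log2 difference, 35S:WIN1 minus vector control, of every tested member of the 18 gene lists. Filled points passed at an adjusted p under 0.05, red above 0 and blue below, open points did not, and the black bar is the list's median. The suberin list had the lowest median of the lists with over 2 members, at -2.25, and in the jasmonate list 14 of 19 members passed above 0.

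Families matched by name in the reference table (TAIR10.1) were compared by Fisher's exact test, with 60 tests adjusted together. The test counts genes as independent, so its p-values are too small where members of a family move together across the arrays. No correlation was estimated for the families, while all list calls by camera were lost with an estimated one. Transcription factors of the WRKY family rose for 26 of 63 matched members (adjusted p = 1.33e-05) and of the AP2/ERF family for 11 of 15 matched members (adjusted p = 1.34e-05). The match by name caught only part of the AP2/ERF family. Of its 15 matched members 0 were lower, while SHN2 and SHN3, the closest relatives of WIN1, were called lower and were not among them. Of all genes tested, 15.1% were higher and 20.2% lower. Genes of glutathione transferases rose for 17 of 46 and fell for 6 (adjusted p = 0.00132 for the higher share). Cytochrome P450 genes were higher for 50 and lower for 45 of 194, and MYB factor genes higher for 33 and lower for 25 of 112. In both families the higher share passed (adjusted p = 6.99e-04 and 6.83e-04) and the lower share did not (0.516 and 0.713). Ribosomal protein genes were lower for 36 of 66 members and higher for none (adjusted p = 4.61e-08), and with a threshold of at least 2-fold this call was lost (adjusted p = 1). Auxin-responsive genes were lower for 32 of 71 (adjusted p = 3.15e-05) and genes of chlorophyll a/b-binding proteins for 13 of 21 (adjusted p = 3.18e-04). No rule was fixed for which families to name. Other protein kinase genes also passed, higher for 48 and lower for 17 of 167 (Fisher adjusted p = 6.85e-05 for the higher share). The 8 families named before them kept their direction and call under quantile normalization, median centring, normexp background correction and the deposited values. Over all families the calls were 19 and, on the deposited values, 11, so other families lost theirs there. On the spike-in scale the auxin-responsive genes lost theirs (Fisher adjusted p = 0.622).

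A run of neighbouring genes on chromosome 3, from AT3G50140 to AT3G50520, differed between the control arrays themselves. It was chosen for description after its values were seen. Of its 26 genes that were well above background on all 35S:WIN1 arrays and on vector control replicate 4, 0, 3 and 10 were above background on vector control replicates 1, 2 and 3. Their median signal was -9.13, -9.26 and -8.27 on those 3 arrays, against -0.74 on vector control replicate 4 and between -0.78 and -0.41 on the 35S:WIN1 arrays. The 10 nearest such genes on each side had medians between -1.68 and -1.15 on all 8 arrays. Windows of 15 neighbouring loci passed a median deviation of 1.5 on the log2 scale only here, among 25449 loci scanned. Of the run's 28 tested genes 22 were called higher in 35S:WIN1, and without the run 7198 genes passed. These 22 calls rest mainly on vector control replicates 1 to 3, so they cannot be put down to the transgene.

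**Figure D4:**
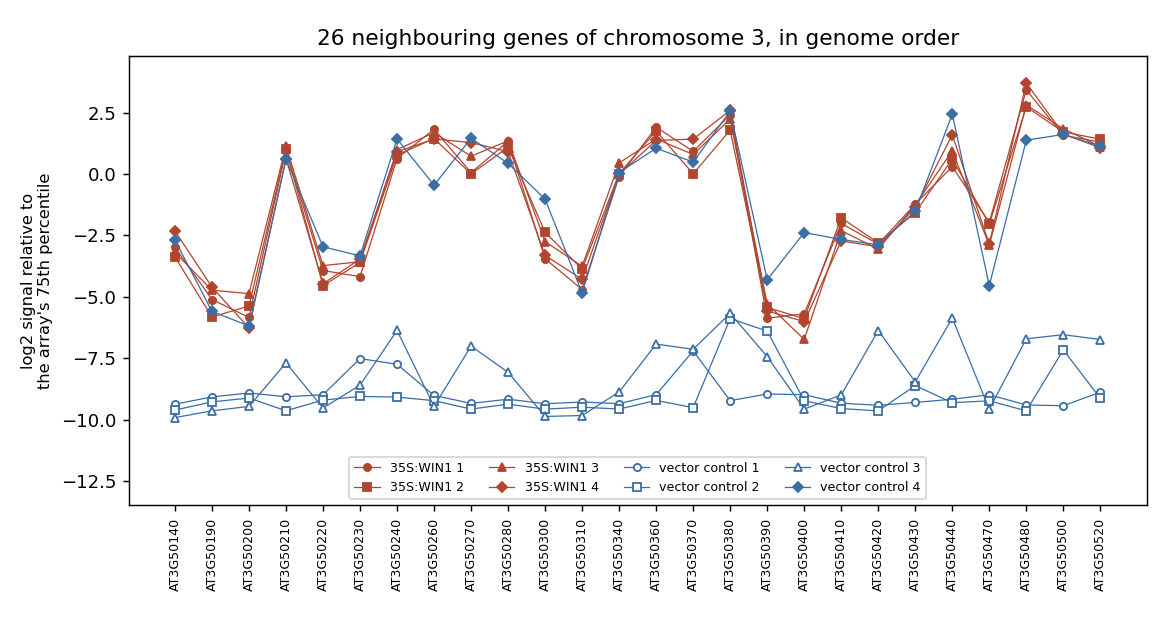
Signal of 26 neighbouring genes of chromosome 3 in genome order on each of the 8 arrays, as log2 relative to the array's 75th percentile. The open blue symbols, vector control replicates 1 to 3, lie far below the filled ones, with medians of -9.13, -9.26 and -8.27 against -0.74 on vector control replicate 4.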

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

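The tests of a wrong label, of a missing chromosome segment, of root tissue and of handling at harvest were chosen only after the result was seen. The touch and wound list was written after WRKY and AP2/ERF genes had been seen to rise, and its part without such families was chosen later still.

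Of 188 sets of 4 values of named genes, 7 had one array far from the other 3, where chance gives about 9.4. On vector control replicate 4, CEJ1 stood at -0.45 against -9.46 to -9.02, AT2G39040 at -3.51 against -2.49 to -2.41, MYB51 at -0.029 against -0.43 to -0.38 and EXPA5 at 2.15 against 1.67 to 1.75. LHCB6 stood at 6.95 on vector control replicate 1 against 6.77 to 6.79, CYP79B2 at 1.92 on vector control replicate 3 against 1.56 to 1.62, and CER6 at 4.64 on 35S:WIN1 replicate 4 against 4.38 to 4.42. Outside the gene tests, 736 of 3067 tested probes without a locus differed between the groups, 188 higher and 548 lower, and 492 of them are named only by a genome position.

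The CEJ1 value belongs to the run of neighbouring genes on chromosome 3 that was near background on vector control replicates 1 to 3. The run's probes were scattered over the array, with a median distance at percentile 87.9 of random probe sets, which argues against a defect of one area, and vector control replicate 4 correlated with its own group at r = 0.972 or more and with no 35S:WIN1 array above 0.927, which argues against a wrong group label. A segment missing from every seedling of replicates 1 to 3 was taken to need 90% of the genes at background on replicates 1 and 2 and the 20 flanking genes above it there, a requirement written after the pattern was seen. It was narrowly missed, by 88.5%, with 18 of 20 flanking genes above background on replicate 1 and 20 of 20 on replicate 2, and also with a first rule for the run's edges, replaced after its result was seen because it stopped at AT3G50480, by 1 flanking gene at background on both, beside 91.7%. A segment missing from most but not all of the material remains open and was not tested. On replicate 3 the 10 genes above background lay at a median of -8.03 (IQR 0.40) on the log2 scale against replicate 4. If such a segment were missing, vector control replicates 1 to 3 would differ from the 35S:WIN1 samples in more than the transgene.

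The fall of suberin genes was set against a lower share of root tissue. The root markers had a median of 0.27 with an interquartile range of 1.37, against -2.25 for the suberin genes. This argues against less root as the whole cause, as far as these 21 markers stand for root tissue. Of them 6 were higher and 2 lower, NRT2.1 at -4.69 among the latter. Genes outside the list, such as FIT1 and IRT1 of iron uptake (-3.26 and -3.85), were not weighed. Of 14 iron deficiency genes 4 were lower and 1 higher. A slide or plate effect cannot be told apart from genotype, and the effect of WIN1 itself stays open as untested.

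Jasmonate genes and CBF1 and CBF2 may have risen through handling at harvest. Of 19 genes known to rise soon after touch or wounding, 18 were higher and none lower, with a median of 3.31 (fry p = 6.45e-06, camera with an estimated correlation adjusted p = 0.0948). Since 11 of them belong to WRKY, AP2/ERF and MYB families already seen to rise, this partly restates that rise, and the other 8 alone had 7 higher and none lower, with a median of 3.19 (fry p = 1.33e-05, camera with an estimated correlation adjusted p = 0.0744). How each group was harvested is not separated from its genotype or slide, so an effect of the transgene stays open as untested.

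The count of 7216 changed genes was reached by 1 of the 35 splits of the 8 arrays, the real one, and the highest of the others gave 1 gene. No share below 1 of 35 can be reached with these splits. Each of the others mixes arrays of both groups, which widens the spread within each part and lowers its count. The splits therefore cannot exclude a chance division of the arrays. A difference between the slides follows the real split and is not excluded either.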

How the results depend on the processing

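The runs without the 2 dimmest arrays, with one control array only, without the chromosome 3 run and on the spike-in scale, and the families under further scalings and backgrounds, were chosen after seeing the data. The count of 7216 changed genes (3078 higher, 4138 lower) stayed within 1.5 times under quantile normalization, median centring, normexp, both other detection filters, the mean over probes, the trend and robust fit and array weights, from 6024 to 8457, and without single arrays, from 5255 to 8335. It moved to 2993 (905 higher, 2088 lower) on the deposited values, 3108 (1581 and 1527) at 2-fold, 3677 (1672 and 2005) at an adjusted p of 0.01, 4318 (1951 and 2367) without 35S:WIN1 replicates 1 and 2, and 427 (300 and 127) with vector control replicate 4 as the only control. The thresholds call fewer genes by construction and the runs on fewer arrays have fewer samples, a lone control being assumed to vary like the other group. The deposited values differ from the main ones in lacking scaling between arrays and in keeping spots with outlier marks, 4 to 99 per array. Left unscaled, the 75th percentile ran from 996.7 to 2490 on the 35S:WIN1 arrays and from 1790 to 2354 on the control arrays. How many calls each difference cost was not tested. The deposited values shift the median of all genes by -0.40, from -0.04 to -0.45. With it the median of the cutin list moves to -0.044, which stays 0.40 above that of all genes (camera adjusted p = 0.0170). The 19 family calls became 11 there. The 10 lists called by camera became 0 with an estimated correlation, 14 with fry and 8 to 13 without single arrays. More than the size of the correlation changes when it is estimated. The seed list's estimate was -0.605, below the preset 0.01, yet its unadjusted camera p rose from 0.0145 to 0.0493. WIN1 kept its direction and call in each setting that could test it, with log2 differences from 9.16 to 13.77, and it was not tested with detection on all 8 arrays. Of 93 other named genes, 17 lost their call on the deposited values, 9 without the 2 dimmest arrays and 59 with one control array, and none reversed. Under the other settings but the spike-in scale the family calls were 16 to 20. On the spike-in scale every difference shifts by -1.64, and 16142 genes passed (305 higher, 15837 lower), with 22 family calls. Ordinary t-tests were used there, after the moderated fit had given 17562 genes (402 and 17160) with infinite prior degrees of freedom, since the shift of each array is shared by all its genes. By ordinary t-tests 6269 genes passed on the main scale. The shift itself put below 0 the medians of the cutin, jasmonate and abscisic acid lists (-1.28, -0.33 and -0.38, not tested) and LACS2, GPAT4, KCS3, CER6, AOS, EDS5, EDS1, CYP79B2, CYP79F2 and THAH (-0.16, -0.049, -0.52, -0.82, -0.59, -0.28, -1.03, -0.36, -0.61 and -0.25), of which none passed. UBQ10, ACT8 and ACT7 (-1.24, -1.35 and -1.50), above 0 before, passed as lower, as did FT and GAPC2, and CYP77A6, CBP60G, ABI1, MYB51, XTH18, THAS1, LEC1 and FUS3 stayed above 0 without passing. Against all other genes tested, the log2 odds ratio of being lower turned negative for cytochrome P450, expansin, xyloglucan endotransglucosylase, UDP glycosyltransferase and MYB genes (-1.59, -1.54, -2.17, -1.20 and -1.05). It did so too for auxin-responsive and ABC transporter genes (-0.33 and -1.02). That of being higher turned negative for other protein kinases (-1.34). A negative value means a smaller share than among the other genes, and does not give the members' own direction. With the replicate number as a block 6041 genes passed, 19 family calls and 10 list calls were made, and of the named genes SOC1 and SEP1 lost their calls (adjusted p = 0.0653 and 0.100). The numbers do not pair the samples: deviations of same-numbered arrays correlated at -0.036, 0.063, 0.14 and 0.041, and only for replicate 3 did both arrays correlate best with their own number. A slide block was not run. Signal over background limits the dimmest transcripts, for which 159 calls rest on a bound.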

Other observations

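The lists below and their tests were chosen after the data were examined. The cytokinin list holds CYP735A2 and the nitrate list holds NRT2.1, both named above as lower. Their set tests therefore partly restate those falls. A list of genes of cytokinin synthesis, cytokinin oxidases, which degrade the hormone, and type-A response regulators, which it induces, had 1 higher and 8 lower of 16, with a median of -0.92 (camera adjusted p = 0.00771, adjusted p = 0.0948 with an estimated correlation). Over the list alone 2 were higher and 10 lower. Without the 3 oxidases none was higher and 7 were lower of 13, with a median of -0.96 (camera adjusted p = 0.00153, adjusted p = 0.0882 with an estimated correlation). The synthesis genes IPT5 and IPT7 stood at 1.11 and 0.62 and did not pass (limma adjusted p = 0.0526 and 0.146), though IPT5 did over the list alone (0.0275). CYP735A1 was at least 11.1-fold lower, and ARR15, ARR4 and ARR7 had log2 differences of -2.78, -1.18 and -1.22, while of the cytokinin oxidase genes CKX5 rose by 1.93, CKX4, above background on 1 of 4 arrays of 35S:WIN1, fell by 3.97 (14.1-fold with values raised to the detection floor), and CKX3 stood at -0.27 and did not pass. Genes of nitrate response and assimilation were 8 lower and none higher of 21, with a median of -0.50 (camera adjusted p = 0.00771, adjusted p = 0.0948 with an estimated correlation). HHO1, above background on 3 of 4 arrays of 35S:WIN1, and NIR1, the nitrite reductase gene, had log2 differences of -4.67 (18.9-fold lower with the floor) and -1.13, while NIA1 and NIA2, the nitrate reductase genes, stood at -0.30 and -0.23 and did not pass.

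Iron deficiency genes did not pass as a set (camera adjusted p = 0.889), and their median of 0.45 and mean of -0.04 differed in sign, with 1 member higher and 4 lower of 14. FIT1, a regulator of iron uptake, NAS1, NAS2 and IRT1, the iron transporter gene, had log2 differences of -3.26, -2.26, -5.02 and -3.85, NAS2 and IRT1 with 2 of 4 arrays of 35S:WIN1 above background and 20.6-fold and 11.2-fold lower with the floor, while PYE rose by 0.82. BHLH38 and BHLH100 stood at 3.60 and 3.65 with SEs of 1.88 and 1.97 and did not pass.

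The spike-in RNAs stood at 4.38, 4.29, 3.82 and 2.77 on 35S:WIN1 replicates 1 to 4 and at 2.78, 2.14, 2.25 and 1.55 on the control arrays, as medians of 8 probes on the log2 scale relative to the array's 75th percentile. Their differences between groups had an SD of 0.52, against 1.04 for the differences of the genes tested.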
